A study of Dictyostelium discoideum with 40 samples.

How the data were processed

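Gene expression was measured on 2-colour Agilent arrays in NC105.1-RFP cells, a red fluorescent derivative of a Dictyostelium discoideum strain. Per the labels' protocols, cells were grown on bacteria, mixed in equal amounts with unlabelled cells and developed on agar. In the chimera the unlabelled partner was the strain NC63.2, and in the control it was NC105.1 itself. Cells were disaggregated after 4, 8, 12, 16 or 20 h, the RFP cells were collected by fluorescence-activated sorting, and their total RNA was amplified and labelled. The purity of the sorted cells is not given in the sources used here. Each of the 10 groups (partner by time) had 2 plates, and the RNA of each plate was hybridised on 2 arrays with the dyes swapped, which gives 20 RNA samples and 40 arrays. The other channel of every array held a common reference, RNA of NC105.1-RFP mixed over the time course. The 2 plates of a group were spread from the same mix of cells, so p-values measure the spread between plates of one mix.

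The deposited scanner files hold the intensity of each spot and of its local background in both channels, made with Agilent Feature Extraction 10.7.3.1 per the file headers. The deposited value table holds log2 ratios of sample over reference, for which the submitters' processing notes name limma without a version. Each of its columns had a correlation of 1 in size with the scanner's processed log ratio of the same array, with the sign turned on the arrays with the sample in Cy3. The scale and the direction of that table are therefore known from the values, and its column medians ran from -0.08 to 0.27. No centring of it is stated.

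From the scanner files, median spot and background intensities were background-corrected with the normexp method (offset 50) and normalized within each array by loess, with control spots at weight 0. The background model was fitted in each channel on spots without an outlier mark of the scanner and then applied to all spots. This differs from fitting it on all spots, and it was chosen after counts from the fit on all spots had been seen. A few spots with very bright local background gave that fit a background SD of up to 4920 intensity units on 1 array, 3 arrays had an SD above 100, and the lowest correlation between the dye-swap arrays of a plate was 0.542 across genes. Fitted on unmarked spots, the largest SD was 17.5 and the lowest such correlation 0.909. Spots dimmer than a background marked as an outlier were left out, 1099 spots over all arrays and at most 330 on one array. The calls under both fits are given in the closing section.

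The arrays hold 43803 spots besides 1417 control spots, for 32199 probes of 10858 loci. Of these loci 10766 matched the reference table of gene names (assembly dicty_2.7, used for names and gene order only) and 92 did not. A symbol other than the locus tag was found for 3247. Outlier spots were left out, log ratios were turned to sample over reference, spots of a probe were averaged, and a probe was kept when its sample channel was well above background on at least 4 arrays, which left 29981 probes. Probes of a gene were averaged (3 probes for 9482 genes, 2 for 563, 1 for 395), and the 2 arrays of a plate were averaged, so n was 2 plates per group. This left 10442 genes. The share of probes well above background ran from 70.8 to 91.8% in the sample channel, no spot was saturated, and the correlation of the plates of a group ran from 0.907 to 0.976 across genes. The number of arrays limits the precision. The median SE was 0.155 (log2) for a difference at one time and 0.069 for the mean over times.

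Linear models were fitted with limma 3.58.1 (with statmod 1.5.0, in R 4.3.3) to all 20 RNA samples, with 1 mean per group, 10 residual degrees of freedom and a shared spread. The contrasts were chimera minus control at each time, the mean of these over the 5 times, an F test of whether the difference varied with time, and F tests of change over time in each partner. P-values were adjusted by the Benjamini-Hochberg method and a gene was called at an adjusted p under 0.05. Adjusted p-values in the report come from these limma fits.

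Before the data were examined, 17 gene lists were fixed and 15 of them had at least 5 measured genes. The lists of discoidin lectins (2 measured genes) and of the hssA family (1) were not tested. The others were tested with camera at a preset correlation of 0.01, and with an estimated correlation. They covered prespore, prestalk, cAMP relay, tgr self-recognition, cell adhesion, counting factor, polyketide, feeding, chaperone, oxidative stress, replication and cell cycle, actin, extracellular matrix, late signalling and ribosomal protein genes. An exact two-sided permutation test of each list's mean over plates within times was added after the data had been seen.

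Named genes were chosen by a rule fixed before the data were examined. As fixed, it also admitted loci with only a product description, but as applied it asked for a symbol, which 3223 of the 10442 genes tested had. For the mean over times the rule took the 10 largest rises and falls among called genes with a symbol whose difference had the same sign at all 5 times, and the 2 largest each way of any kind. At each time it took the 4 largest each way with a symbol and the largest of any kind, among called genes whose chimera plates both lay on one side of both control plates, a separation that chance gives for 33.3% of genes. It took the 8 smallest p of the F test of the difference over time, the 5 largest changes each way in the control from 4 to 20 h, markers, and called list members. Where fewer than 5 genes were called, the 5 smallest p were taken. The marker carA was not matched. Where no array of a group had a probe of a gene well above background, the difference is given as a bound ("at least N-fold"). The bound sets the bright group's mean level against the higher, per array, of the dim probe's signal and the lowest signal well above background, on log2 levels after loess and Aquantile. It is a point value of mean levels without an error. It allows for the dim signal and not for the spread between plates, so it is not a confidence limit.

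The alternatives were no background correction, Agilent's processed signals, the deposited values, median centring, Aquantile scaling, other filters on dim probes, the brightest probe per gene, 1 dye only, all 40 arrays with the plate as a random block, the slide or replicate number as a block, each time fitted alone, and each plate left out. The arrays lay on 6 slides scanned on 3 days, with at most 4 arrays per slide and day, as the file headers give them. Those headers put 2 arrays at one slide and position for 16 of the 20 plates, the dye-swap pair of a plate on different days, so that the 40 arrays share 24 places and the recorded slide may not be the physical one on both days. A slide effect was modelled by the slide of the plate's Cy5 array, which groups the plates in 5 as the slides of both arrays do, and what it stands for is limited by that doubt. No slide held chimera and control plates of the same time, so no difference can be given within a slide. The arrays with the sample in Cy5 were all scanned on day 1, so the fit on them is a value within one scan day. The fit was tested on simulated data made from these arrays, with 200 of the 10442 genes changed. For the mean over times, a difference of 0.5 (log2) was recovered for 89.6% of genes, 1 for 98.5% and 2 for 100%. These were 60, 66 and 66 genes, beside 20 false calls. For 4 h the shares were 28.4, 71.6 and 87.9%, or 19, 48 and 58 genes, beside 10 false calls. In both cases the false share of the calls lay above the adjusted p threshold. The recovery does not by itself show how the fit treats genes or plates that vary together.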

Results

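The arrays followed RFP-labelled NC105.1 cells through development at 5 time points. The cells had developed either beside cells of another strain, NC63.2 (chimera), or beside unlabelled cells of their own strain (control). The title of the series names the question as cooperation with self against non-self. Each of the 10 groups had 2 plates with 2 dye-swapped arrays each. Values are log2 ratios of the sorted cells' RNA over a common reference, and differences are chimera minus control with the SE of the limma fit.

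In the control, development was the main source of change. From 4 to 20 h all 15 measured prestalk genes and 10 of 13 prespore genes rose, and 71 of 72 ribosomal protein genes fell. These lists were called by camera but not with an estimated correlation (adjusted p = 0.0948 for prestalk genes and 0.405 for the others). The largest rises with a symbol were those of 7E (8.08 ± 0.34, log2 and SE), ecmD (7.96 ± 0.32), hssB (7.85 ± 0.44), st15 (7.59 ± 0.22) and ecmA, a prestalk extracellular matrix gene (7.50 ± 0.38). The prestalk marker ecmB rose by 6.59 ± 0.36, the spore coat genes cotB and cotC by 3.99 ± 0.39 and 6.17 ± 0.52, the prespore surface gene pspA by 3.83 ± 0.46 and the spore gene spiA by 5.76 ± 0.67. The largest falls with a symbol were those of cad3 (-5.75 ± 0.42), the chitobiase gene ctbsB (-4.29 ± 0.28), ppt3 (-3.85 ± 0.18), rps12 (-3.81 ± 0.24) and prtA (-3.66 ± 0.30). The cell adhesion gene csaA fell by 1.56 ± 0.16 and the allorecognition gene tgrB1 by 1.43 ± 0.30 on the log2 scale. For tgrC1 (-0.54 ± 0.33, adjusted p = 0.161), acaA (0.11 ± 0.19, 0.601), pdsA (-0.37 ± 0.21, 0.139) and cprD (0.08 ± 0.21, 0.744) no difference between 20 and 4 h passed the test.

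Of the 10442 genes tested, 8442 varied with time in the control and 8833 in the chimera, and 7916 were called in both. Between 4 and 20 h, 3910 genes rose and 3675 fell in the control. In the chimera 7805 genes differed between these times. Of the genes called in both partners, 6675 had the same direction and 46 the opposite one. All 15 measured prestalk genes rose in the control (median 4.52), as did 13 of 15 extracellular matrix genes (5.23), 10 of 13 prespore genes (3.99) and 12 of 21 tgr genes (0.46), while the prespore list members psiB (-2.58 ± 0.29), cbpB (-1.09 ± 0.14) and pspC (-1.05 ± 0.10) fell. Of 72 ribosomal protein genes 71 fell (-2.41), rpl10a rose (0.59 ± 0.21), and 19 of 28 actin genes fell (-0.86), with the same counts when adjusted over the list alone. These 6 lists were called by camera, at adjusted p = 6.84e-08, 0.000283, 0.028, 0.0275, 3.85e-18 and 0.00219. With an estimated correlation no list was called, with adjusted p = 0.0948 for the prestalk and matrix lists and 0.405 for the others.

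**Figure D1:**
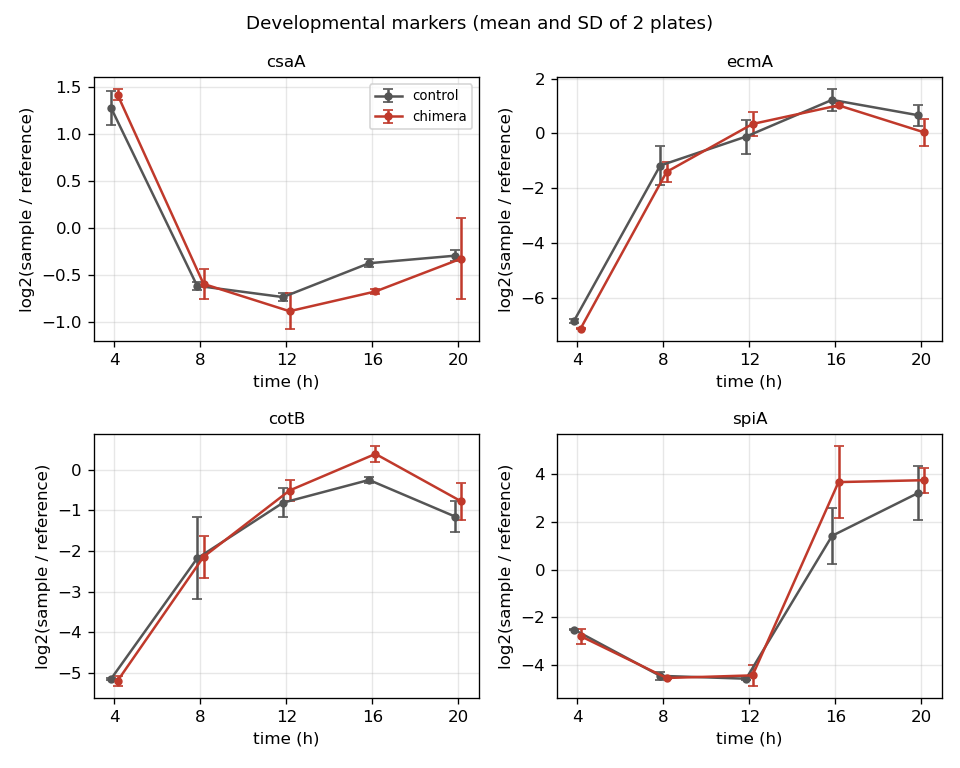
Log2 ratio of sample over reference (vertical axis) against time of development in hours for 4 developmental markers, as mean and SD of 2 plates, control in grey and chimera in red. For csaA, ecmA and cotB the differences between chimera and control lie between -0.64 and 0.63, and spiA at 16 h was 3.68 ± 1.51 in the chimera and 1.42 ± 1.19 in the control (adjusted p = 0.153).

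Averaged over the 5 times, cells from the chimera had far more RNA of 2 neighbouring loci than cells from the control. DDB_G0288417 was higher by 5.24 ± 0.27 (log2, 37.6-fold, adjusted p = 4.5e-07), with signal well above background on 20 of 20 chimera arrays and 9 of 20 control arrays, so its size rests in part on control signals near background. DDB_G0288419 was at least 28.8-fold higher (adjusted p = 5.18e-08), since none of the control arrays had it well above background. Outside the rule for naming, and chosen after their values were seen, DDB_G0272706 was higher by 4.71 ± 0.28 (adjusted p = 1.25e-06, 1 of 20 control arrays well above background), DDB_G0272716 by 2.64 ± 0.17 (2.6e-06, 13 of 20) and DDB_G0278667 at least 6.6-fold (2.94e-05, 0 of 20). The size given for DDB_G0272706 rests on control signals near background. The genes named next differed by less than 2-fold in the mean. Among called genes with a symbol and the same sign at all 5 times, the largest rises were those of abcA5, an ABC transporter gene (0.82 ± 0.17), cdc25 (0.61 ± 0.12) and gnt11 (0.59 ± 0.09). Smaller rises were found for cbpI (0.43 ± 0.10), bzpN (0.38 ± 0.09), tmem56A (0.37 ± 0.08), the cytochrome P450 gene CYP508C1 (0.36 ± 0.07), splB (0.32 ± 0.07), tpsC (0.30 ± 0.08) and the purine synthesis gene purL (0.28 ± 0.06). The same sign at all times does not mean an even size. The difference of gnt11 was 0.06 at 4 h and 1.6 at 16 h, and that of CYP508C1 was 1 at 4 h and 0.04 at 16 h. That of cdc25 was more even, from 0.44 at 20 h to 0.95 at 16 h.

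The largest falls were those of DDB_G0274895 (-0.78 ± 0.09) and DDB_G0278287 (-0.63 ± 0.09). With a symbol the falls under that limit were led by apeA (-0.62 ± 0.12), the ribosomal protein genes rps12 (-0.52 ± 0.11) and rpl14 (-0.36 ± 0.07), mnd1, a gene named for meiotic nuclear division (-0.46 ± 0.10), the superoxide dismutase gene sodB (-0.44 ± 0.08) and cnrG (-0.41 ± 0.04). The value of cnrG rests on 2 probes, with signal well above background on 11 of 20 chimera and 16 of 20 control arrays. The DNA damage checkpoint genes rad1 (-0.38 ± 0.07) and rad9 (-0.37 ± 0.08), chdh (-0.37 ± 0.09) and the amylase gene amyA (-0.37 ± 0.09) fell as well. The falls named here were not even over time, and each was largest at 4 h. The difference of apeA was -1.96 at 4 h and -0.16 to -0.47 later. For mnd1 it was -1.42 and -0.05 to -0.5, and for rad9 -0.97 and -0.13 to -0.42. DDB_G0274895 and cnrG fell nearly as much at 16 h (-1.44 and -0.63) as at 4 h (-1.5 and -0.73). Adjusted p for these named genes ran up to 0.0496, for tpsC.

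In all 345 genes were called for the mean over times, 184 higher and 161 lower in the chimera, and 11 of them differed by over 2-fold. The balance of directions depended on the processing. It was 182 higher and 166 lower without background correction, 121 and 145 with Agilent's processed signals, and 250 and 265 with a replicate block common to all times. With the slide as a block 65 genes were called (47 higher and 18 lower), all among the 345, and of the 24 genes named above by the rule 6 were still called (DDB_G0288417, DDB_G0288419, gnt11, DDB_G0274895, DDB_G0278287 and cnrG). Chimera and control were balanced over slides, so no difference for the mean moved with the block, while the residual degrees of freedom went from 10 to 6 and the median SE from 0.069 to 0.071. With the 4 h difference left out of the mean but all plates kept in the fit, the mean over 8 to 20 h called 60 genes (55 higher and 5 lower). The count for the mean over 5 times also moved when a single plate was left out, as given in the closing section.

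Ribosomal protein genes were lower in the chimera as a group (median -0.28 over 72 genes, camera adjusted p = 4.86e-24, and 0.64 with an estimated correlation), and all 72 members had a difference below 0. Over all genes tested 2 of them fell, rps12 and rpl14, and 61 fell when adjusted over the list alone. Replication and cell cycle genes were shifted up (median 0.14 over 29 genes, adjusted p = 0.00448, and 0.64 with an estimated correlation), although the one member called over all genes, orcB, fell (-0.35 ± 0.05). Adjusted over the list alone, 4 rose and 1 fell. Actin cytoskeleton genes were shifted down (median -0.08 over 28 genes, adjusted p = 0.0336, and 0.64 with an estimated correlation) with 0 members called on either basis. The actin call was lost with median centring (median -0.02, adjusted p = 0.707), with Agilent's processed signals (-0.10, 0.121), with the deposited values (-0.10, 0.122) and without any one of 9 of the 20 plates, and the replication call without either of 2 plates. In the exact permutation test the ribosomal list had p = 0.00823 (adjusted 0.123, lower in the chimera at 5 of 5 times). The estimated correlation between genes was 0.885 for the ribosomal list, 0.433 for the replication list and 0.19 for the actin list, against the preset 0.01. Members of a list are thus not independent, and the camera p-values at the preset correlation, here and at single times, overstate the evidence.

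The other 12 lists did not pass camera for the mean over times. Medians were 0.23 for prespore genes (adjusted p = 0.209), 0.07 for prestalk genes (0.158), 0.09 for extracellular matrix genes (0.271), 0.05 for late signalling genes (0.158) and -0.04 for cAMP relay genes (0.306). They were 0.02 for tgr self-recognition genes (0.721), 0.03 for cell adhesion genes (0.788), -0.12 for counting factor genes (0.306), 0.04 for polyketide genes (0.589), -0.09 for feeding genes (0.158) and -0.02 for chaperone genes (0.589). The 13 oxidative stress genes had a median of 0.08 (0.606). Of these prdx4 rose (0.24 ± 0.06) and sodB fell over all genes tested, and 2 rose and 2 fell when adjusted over the list alone.

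At 4 h the chimera and the control differed at many genes. The calcium-binding protein gene pefA was higher in the chimera by 1.99 ± 0.27 (3.97-fold), the cytochrome P450 gene CYP514A1 by 1.68 ± 0.41, gmsA by 1.61 ± 0.18 and the Argonaute family gene agnB by 1.57 ± 0.16. DDB_G0288417 was higher by 4.38 ± 0.60, with 2 of 4 control arrays well above background, so its size rests in part on control signals near background. Among called genes whose chimera and control plates did not overlap, the largest fall was that of DDB_G0282833 (-2.79 ± 0.53). With a symbol the largest falls were those of apeA (-1.96 ± 0.27), mnd1 (-1.42 ± 0.23), tmem33 (-1.33 ± 0.17) and pdiA (-1.21 ± 0.26). The gene pdiA encodes an inhibitor of the extracellular cAMP phosphodiesterase. Loci without a symbol fell by more than some of these, such as DDB_G0272436 (-2.52 ± 0.12) and DDB_G0274895 (-1.5 ± 0.21). The plate values of agnB were 0.11 ± 0.16 in the chimera and -1.45 ± 0.13 in the control (mean and SD, n = 2 plates).

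**Figure D2:**
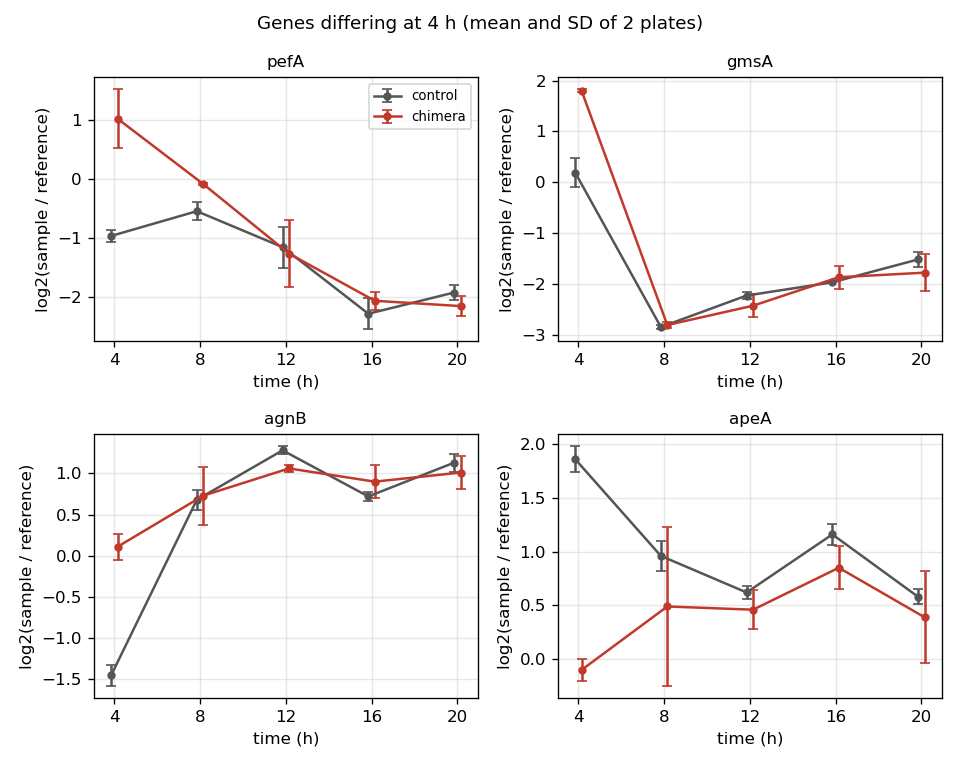
Log2 ratio of sample over reference against time in hours for 4 genes called at 4 h, as mean and SD of 2 plates, control in grey and chimera in red. At 4 h pefA, gmsA and agnB lie higher and apeA lower in the chimera, and at the later times the differences are between -0.47 and 0.47.

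Adhesion and actin genes were among those that differed at 4 h, when 13.59% of all genes tested were called. The share of called members lay above that for adhesion genes and below it for actin and ribosomal protein genes. Of 20 cell adhesion genes 6 rose and 2 fell (median 0.31, camera adjusted p = 0.0116, 0.917 with an estimated correlation, and 0.0582 at a median of 0.43 with the slide as a block), and 8 rose and 2 fell when adjusted over the list alone. The rises included the substrate adhesion gene sadA (0.76 ± 0.12), the integrin beta-like genes sibE (0.81 ± 0.15) and sibB (0.47 ± 0.11), the talin gene talA (0.68 ± 0.18), ampA (0.89 ± 0.24) and cad3 (1.38 ± 0.42), and the falls were phg1a (-0.45 ± 0.10) and phg1b (-0.53 ± 0.10). Of 28 actin cytoskeleton genes 3 rose, fimA (0.74 ± 0.22), the profilin gene proA (0.99 ± 0.27) and talA, and 3 did so when adjusted over the list alone (median 0.33, adjusted p = 0.0016, and 0.917 with an estimated correlation). Of the 72 ribosomal protein genes 5 fell and 0 when adjusted over the list alone (median -0.40, adjusted p = 1.28e-08, and 0.942 with an estimated correlation). The ribosomal call was lost with the background model fitted on all spots (median -0.11, adjusted p = 0.0914), and the median was -0.72 with the slide as a block. Without chimera plate 2 of 4 h the adhesion (median 0.18, adjusted p = 0.133) and actin (0.16, 0.133) calls were lost and the ribosomal median was -0.23, without control plate 2 the adhesion median was 0.48, and without control plate 1 the adhesion call was lost (0.21, 0.139).

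Replication and cell cycle genes went both ways at 4 h. The cyclin genes cycD (1.13 ± 0.12), cycA (0.83 ± 0.15) and cycB (1.19 ± 0.29) rose, and orcB (-0.84 ± 0.11), polD1 (-0.65 ± 0.14), rfc5 (-0.54 ± 0.15) and mcm2 (-0.55 ± 0.16) fell, with a list median of -0.01 (adjusted p = 0.85). The list's mean was 0.03. The superoxide dismutase gene sodC rose by 1.09 ± 0.13 while sodB fell by 0.93 ± 0.17 (log2). Of 21 tgr self-recognition genes 0 were called at 4 h (median 0.06, adjusted p = 0.85).

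In all 1419 genes were called at 4 h, 767 higher and 652 lower in the chimera, and 212 of them by over 2-fold. A fit with the slide as a block called 386 genes, 361 of them among the 1419, and CYP514A1 (adjusted p = 0.157), pdiA (0.121) and DDB_G0282833 (0.0752) were no longer called. Their differences with the block were 1.68 ± 0.59, -1.09 ± 0.34 and -2.77 ± 0.73. All 1419 genes kept their direction with it, at a median of 106% of the size without it, while the median SE went from 0.155 to 0.206. Leaving out chimera plate 2 of 4 h gave 580 genes, control plate 2 gave 625 and chimera plate 1 gave 857.

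**Figure D3:**
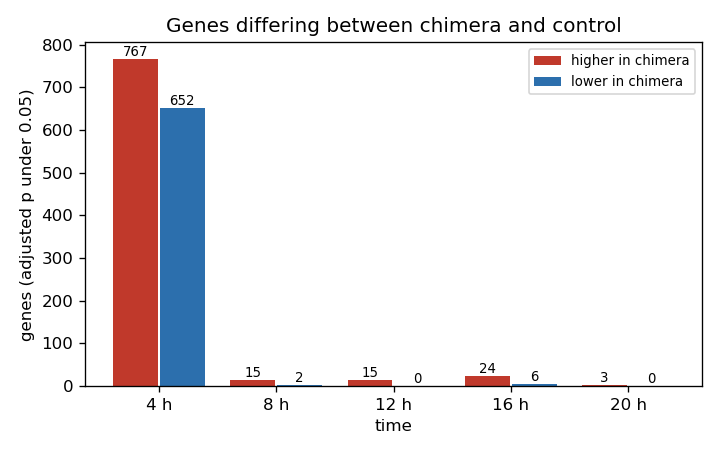
Number of genes called (adjusted p under 0.05, of 10442 tested) at each time in hours, higher in the chimera in red and lower in blue. At 4 h 767 genes were higher and 652 lower, and at 20 h 3 were higher and 0 lower.

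At 8 and 12 h few genes were called, and nearly all of them were higher in the chimera. An unadjusted p under 0.05 in the limma fit was found for 378 genes at 8 h and 355 at 12 h. Both lie below the share of 0.05 of all 10442 that chance alone would give, so differences may have been missed. DDB_G0272706 was at least 119-fold higher at 8 h (adjusted p = 0.000178) and at least 83.1-fold higher at 12 h (adjusted p = 0.000406), and DDB_G0288419 at least 52.3-fold at 8 h (adjusted p = 0.00015). DDB_G0288419 was higher at 12 h as well (adjusted p = 2.62e-05), with no fold given because its bound from channel levels lay above the fold of the ratios. At either time 0 of 4 control arrays had the 2 loci well above background, so they are not ranked. The one named fall at 8 h was DDB_G0294441 (-1.22 ± 0.17, from 1 probe). At 8 h 15 genes were higher and 2 lower, and at 12 h 15 were higher and 0 lower. Of these, 12 genes were higher at both times, where independent lists would share 0.0215. A slide block left 7 genes called at each time, and DDB_G0294441 was no longer called (-1.39 ± 0.22 with the block, adjusted p = 0.13). The median size of the called differences with it was 110% at 8 h and 115% at 12 h of that without it. Leaving out either control plate of 8 h gave 7 genes at 8 h, and leaving out control plate 2 of 12 h gave 9 at 12 h.

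Replication and cell cycle genes were shifted up at 8 h (median 0.42, camera adjusted p = 3.7e-23, and 0.145 with an estimated correlation). None of the 29 was called over all genes, and 10 rose and 1 fell when adjusted over the list alone. Ribosomal protein genes were shifted down at 8 h (median -0.32, adjusted p = 3.01e-22, and 0.422 with an estimated correlation) and at 12 h (median -0.24, adjusted p = 6.57e-10, and 0.446). The replication median at 8 h was 0.26 without control plate 1 of 8 h. The ribosomal median at 8 h was -0.17 with median centring, -0.16 without control plate 1 of 8 h, and -0.15 and -0.49 without chimera plates 1 and 2 of 8 h, all of them called. Feeding genes were shifted down at 8 h (median -0.09, adjusted p = 0.0459, and 0.422), a call that 7 of 15 other settings ended and that turned to a median of 0.03 (0.767) without control plate 2 of 8 h. At 12 h prespore genes (median 0.30, adjusted p = 0.0429), prestalk genes (0.28, 0.00306) and extracellular matrix genes (0.23, 0.0163) were shifted up and actin genes down (-0.16, 0.00306), each at adjusted p = 0.446 with an estimated correlation. The 12 h calls of all 5 lists were lost with the slide as a block, with medians of 0.03 for prespore genes (adjusted p = 0.902), 0.09 for prestalk (0.826), 0.03 for matrix (0.769), -0.06 for actin (0.504) and -0.06 for ribosomal protein genes (0.397). All 5 were lost as well without control plate 1 of 12 h, where the ribosomal median was -0.01 (0.745), and all but the ribosomal one (-0.12) without chimera plate 2 of 12 h. Without control plate 2 of 12 h the medians of prespore, prestalk, matrix and ribosomal genes were 0.555, 0.45, 0.445 and -0.45, and without chimera plate 1 those of prespore, matrix and ribosomal genes were 0.49, 0.35 and -0.36. In the lists shifted at 8 and 12 h other than the replication list, 0 members were called over all genes and 0 over the list alone.

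At 16 h gnt11 rose by 1.60 ± 0.21 (3.04-fold), the urocanate hydratase gene uroc1 by 1.15 ± 0.19, nxnB by 0.62 ± 0.11 with 2 of 4 control arrays well above background, and the peroxisome gene pex11 by 0.52 ± 0.09. DDB_G0288419 was at least 85.2-fold higher (adjusted p = 3.98e-05). The falls named by the rule were those of DDB_G0274895 (-1.44 ± 0.21), the histone H3 variant gene H3v1 (-0.90 ± 0.15), cnrG (-0.63 ± 0.10) and the phospholipase D gene pldZ (-0.61 ± 0.11). In all 24 genes were higher and 6 lower. A slide block left 3 genes called, of those named here only DDB_G0288419 (adjusted p = 0.004). The other differences stayed of like size with larger errors, such as 1.60 ± 0.27 for gnt11, 1.15 ± 0.25 for uroc1, -1.13 ± 0.23 for DDB_G0274895 and -0.88 ± 0.23 for H3v1, and the median over the 30 called genes was 104% of the size without the block. Leaving out chimera plate 1 of 16 h gave 204 genes and leaving out control plate 2 of 16 h gave 5.

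Among the lists at 16 h, actin genes were shifted down (median -0.34, camera adjusted p = 9.56e-07, and 0.551 with an estimated correlation), with 0 of 28 called over all genes and 8 lower and 1 higher when adjusted over the list alone. Ribosomal protein genes were shifted down (median -0.29, adjusted p = 5.26e-09, and 0.601) with 0 called on either basis, but not with the slide as a block (median 0.008, adjusted p = 0.978). Median centring gave -0.22 for actin and -0.155 for ribosomal protein genes, and without chimera plate 2 of 16 h the ribosomal median was -0.19. Prestalk genes were shifted up (median 0.23, adjusted p = 0.0118, and 0.582), with 0 called over all genes and 3 higher when adjusted over the list alone. That call too was lost with the slide as a block (median 0.28, adjusted p = 0.152) and without chimera plate 2 of 16 h (0.15, 0.0632). Across genes outside the ribosomal list, the difference between chimera and control at 16 h had a correlation of 0.714 with the control's own change from 12 to 20 h (genes are not independent replicates). Most genes named at 16 h differed in the direction of that change. The control of gnt11 went from -2.28 at 12 h to -0.15 at 20 h, and that of H3v1 from 0.62 to -0.81. The fall of cnrG went against it (0.30 and 0.60). A stage difference and an effect of the partner cannot be told apart for these genes.

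At 20 h 3 genes were called, all higher in the chimera. DDB_G0288419 was at least 24.2-fold higher (adjusted p = 0.00047). DDB_G0288417 was higher by 4.52 ± 0.60 (adjusted p = 0.0268), with 1 of 4 control arrays well above background, and DDB_G0272716 by 2.76 ± 0.38 (adjusted p = 0.0293), with 2 of 4. The sizes of both rest in part on control signals near background. The next in order of p, DDB_G0272706 (adjusted p = 0.144) and DDB_G0277099 (0.54 ± 0.09, adjusted p = 0.15), did not pass. At an unadjusted p under 0.05 there were 235 genes, below the share of 0.05 of all 10442 that chance alone would give. With the slide as a block limma called 0 genes, and 309 had an unadjusted p under 0.05, also below that share. Such counts mean that the p-values ran larger than chance alone would give. Neither count therefore shows that further differences are absent. The differences of DDB_G0288417 and DDB_G0272716 were then 3.52 ± 0.66 and 2.50 ± 0.42, and DDB_G0288419 had an adjusted p of 0.0978. Leaving out any one control plate or either chimera plate of 12 h gave 1 gene, and leaving out chimera plate 1 of 20 h gave 7.

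Also at 20 h, camera called actin genes (median -0.19, adjusted p = 4.56e-07, and 0.451 with an estimated correlation), ribosomal protein genes (-0.16, 6.31e-07, and 0.602), cAMP relay genes (-0.22, 0.00661, and 0.602) and cell adhesion genes (-0.10, 0.046, and 0.602), all shifted down. None of their members was called, over all genes or over the list alone. Without chimera plate 2 of 20 h the ribosomal genes were shifted up (median 0.13, adjusted p = 0.00466) and the actin call was lost (-0.06, 0.132), without chimera plate 1 of 20 h the cAMP relay (-0.05, 0.61) and adhesion (-0.03, 0.671) calls were lost, and 9 of 15 other settings ended the adhesion call. Without chimera plate 1 the ribosomal median was -0.45 and the actin median -0.34, without control plate 1 the actin median was -0.11 and the cAMP relay median -0.10, and without control plate 2 the actin median was -0.33.

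**Figure D4:**
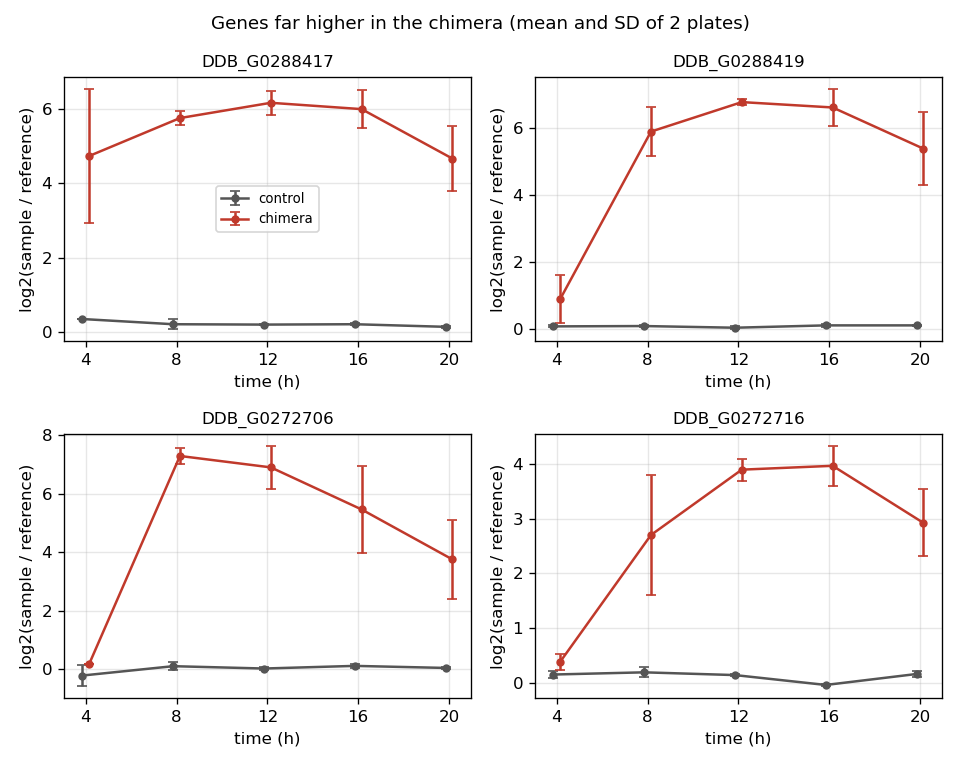
Log2 ratio of sample over reference against time in hours for 4 loci far higher in the chimera, as mean and SD of 2 plates, control in grey and chimera in red. The control lies near 0 throughout, while DDB_G0288417 is already at 4.73 ± 1.8 in the chimera at 4 h and the other 3 loci lie far above the control from 8 h on.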

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

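The tests of partner RNA, of a shared genome segment and of its neighbours, and of the size of the 4 h differences with the slide as a block, were chosen only after the result had been seen. The slide tests of the mean over times were set aside, and the stage test of the ribosomal genes was held against its spread, after their values were known.

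The difference between chimera and control varied with time for 195 genes (limma's F test of the difference over time, adjusted p under 0.05). The same test with the slide as a block called 0 genes, with 846 at an unadjusted p under 0.05, so none of the differences over time below passed with it, although DDB_G0272436 was then still at -2.68 ± 0.16 at 4 h. Leaving out a single plate gave from 28 genes (control plate 2 of 4 h) to 280. The smallest adjusted p was that of DDB_G0272436 (0.000124), which differed by -2.52 ± 0.12 at 4 h, -0.71 ± 0.12 at 8 h and 0.02 ± 0.12 at 20 h. For DDB_G0282685 (adjusted p = 0.000823) the difference was 1.29 ± 0.09 at 4 h and -0.22 ± 0.09 at 20 h, and for DDB_G0280349 (0.00317) it was 1.05 ± 0.08 and 0.02 ± 0.08. The adjusted p was 0.00494 each for DDB_G0283577, DDB_G0288003, DDB_G0288419, the G protein alpha gene gpaL (1.34 ± 0.12 at 4 h and -0.16 ± 0.12 at 20 h) and the copine gene cpnE (1.20 ± 0.11 and -0.15 ± 0.11). It was 0.0343 for pefA, 0.00985 for gmsA, 0.00795 for agnB and 0.0273 for tmem33, all named for 4 h. The histone variant gene H3v1 (0.0209) differed by -1.09 ± 0.15 at 4 h, 0.14 ± 0.15 at 12 h and -0.90 ± 0.15 at 16 h. The adjusted p was 0.0176 for uroc1, 0.044 for DDB_G0274895, 0.00817 for DDB_G0272706, 0.0146 for DDB_G0272716 and 0.0155 for DDB_G0277099.

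A set of 10 loci was near background in the control and above it in the chimera (well above background on at most 2 of 20 control arrays and at least 10 of 20 chimera arrays, bounds set after the data were seen), among them DDB_G0288419, DDB_G0272706 and DDB_G0278667 (at least 6.6-fold higher), and 0 loci went the other way over all genes tested. Added RNA of the partner strain in the sorted cells predicts such a one-sided set, which only just reached the 10 loci that test asked for, and the purity of the sort on RFP, meant to remove partner cells, is not given in the sources used here. Against one genome segment, the set lies on 5 chromosomes of the reference and held 0 pairs of loci within 10 genes of each other, although 4 of its members had a called locus higher in the chimera within 10 genes (5 such loci outside the set, among them DDB_G0288417 and DDB_G0272716), a number that 19.4% of 10000 random sets reached, and several segments are not excluded. The slide block called 10 of 10, but chimera and control were balanced over slides, so the mean difference could not move and that test decides nothing. Induction in the chimera could give the same set, was not tested, and stays open.

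Far more genes were called at 4 h (1419) than at any later time. At 8, 12 and 20 h fewer genes than chance alone would give had an unadjusted p under 0.05. The counts at those times may thus be too low. If the chimera plates were at another stage, the difference at 4 h would follow the control's change from 4 to 8 h. Across the genes called at 4 h that correlation was -0.188 (-0.107 and -0.269 with the control plates exchanged), between the bounds set for either outcome, so a stage difference and an effect of the partner cannot be told apart here. The slide block called 386 genes at 4 h, between the bounds set beforehand for a count, but all 1419 genes kept their direction with it, at a median of 106% of the size without it (101 to 112% with each plate left out), and at the later times it called at most 7. These sizes argue against an additive effect of the recorded slide, and the calls ended with a median SE of 0.206 in place of 0.155 and 6 residual degrees of freedom in place of 10.

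The ribosomal protein genes were lower in the chimera at 5 of 5 times, although the list was called neither with an estimated correlation nor by permutation, and without chimera plate 2 of 20 h it was called higher at 20 h (median 0.13). In the control these genes were lower at 20 h than at 4 h, so a chimera that is further on could show the same shift at times when they fall. With the control's trend removed, 86.5% of the list's median difference was left over 8, 12 and 16 h (87.7, 102 and 72.4%, SD 14.8), above the bound of 80% set beforehand but by less than the spread, so a stage difference stays open. At 12 h removing the trend took nothing off the shift, and this test did not cover 4 and 20 h. The slide block kept 100% of the mean shift by the balance of the design, which tests nothing, while at the single times the median with it was -0.72 at 4 h, -0.46 at 8 h, -0.06 at 12 h, 0.008 at 16 h and -0.18 at 20 h, so the slide stays open for 12 and 16 h. An effect of the partner strain stays open as well.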

How the results depend on the processing

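The fit of the background model on all spots, the mean over 8 to 20 h, the permutation of lists and the look at list medians of single times were chosen after the data had been seen. No count of genes varying with time in either partner moved by over 1.5 times. Of the genes picked by size, smallest p or as markers for the mean, a single time or the control's 4 to 20 h change, none that was called changed sign in any alternative. Genes named only as list members, for the difference over time or outside the rule were not followed through all alternatives. Of the list medians called for the mean or a single time, 3 changed sign in an alternative, those of ribosomal protein genes at 16 h with the slide as a block (0.008), of feeding genes at 8 h without control 8 h plate 2 (0.033, from -0.229 without chimera 8 h plate 2) and of ribosomal protein genes at 20 h without chimera 20 h plate 2 (0.13, from -0.448 without chimera 20 h plate 1). The cause of the changes below was not tested, except where fewer plates or probes entered. With the slide as a block, limma called 65 genes for the mean over times (345 without), 386 at 4 h (1419), 7 at 8 h (17), 7 at 12 h (15), 3 at 16 h (30), 0 at 20 h (3) and 0 for the difference over time (195). The background model fitted on all spots gave 173 for the mean, 917 at 4 h, 14 at 16 h, 1 at 20 h and 40 for the difference over time. Median centring gave 133 for the mean, 9 at 8 h (9 higher and 0 lower, against 15 and 2), 8 at 12 h, 7 at 16 h and 5 lists (3 with loess), the actin list not among them. Agilent's processed signals and the deposited values, which are nearly the same values, each gave 17 at 16 h and 7 at 20 h. Cy5 arrays alone, all of one scan day, gave 188 for the mean and 9 at 16 h, and Cy3 arrays alone 10 at 8 h, 1 at 20 h and 128 for the difference over time. A dim filter that kept probes well above background on at least 20 arrays gave 6 at 8 h, 6 at 12 h and 5 at 16 h, and the brightest probe 14 at 16 h. All 40 arrays with the plate as a random block gave 726 for the mean, 437 at 16 h, 1 at 20 h and 577 for the difference over time. Each time alone gave 8 at 8 h, 6 at 12 h, 3 at 16 h and 0 at 20 h (118 at an unadjusted p under 0.05, below the share of 0.05 that chance alone would give). The mean over 8 to 20 h called 60. Lists called for the mean fell to 0 with an estimated correlation (0 at an unadjusted p under 0.05) and to 0 by exact permutation (1). Aquantile scaling leaves ratios unchanged by construction.

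Plates with the same replicate number deviated together at 4 h (r = 0.552 across genes), 8 h (0.475), 12 h (0.586) and 20 h (0.786) but not at 16 h (-0.183), so the numbers were not taken to pair plates. Where plates deviated together, the main fit keeps that shared part in its spread, and its counts depend on this choice. A replicate block within each time gave 1822 genes for the mean, 2733 at 4 h, 35 at 12 h, 215 at 16 h and 742 for the difference over time. A replicate block common to all times gave 1 at 20 h.

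When a plate is left out, the lone plate of its group is assumed to vary like the others. For the mean the count ran from 116 to 949. It was 182 without control 4 h plate 2, 227 and 154 without chimera 4 h plates 1 and 2, 168 without chimera 8 h plate 1, 161 without control 12 h plate 1, 148 without chimera 12 h plate 2, 150 without control 16 h plate 2, 116 without chimera 16 h plate 2, 124 and 193 without control 20 h plates 1 and 2, and 949 and 220 without chimera 20 h plates 1 and 2. At 4 h it ran from 580 (without chimera plate 2) to 1662, with 625 without control plate 2 and 857 without chimera plate 1. At 8 h it ran from 7 (without either control plate) to 20, with 10 without chimera plate 1, and at 12 h from 9 (without control plate 2) to 19. At 16 h it moved for every plate, from 5 (control 16 h plate 2) and 7 (chimera 16 h plate 2) to 129 (control 16 h plate 1) and 204 (chimera 16 h plate 1). It was 55 without either chimera 20 h plate, and 9 to 19 without any other, which were 15 (control 4 h), 12 (chimera 4 h), 19 (control 8 h), 10 (chimera 8 h), 9 (control 12 h), 15 (chimera 12 h) and 11 (control 20 h). At 20 h it was 1 without any one control plate or either chimera 12 h plate and 7 without chimera 20 h plate 1. For the difference over time it ran from 28 (without control 4 h plate 2) to 280, with 101 (control 4 h plate 1), 82 and 38 (chimera 4 h plates 1 and 2), 125 (control 16 h plate 2), and 118 and 128 (control 20 h plates 1 and 2). Lists called ran from 2 to 7, with 7 without control 4 h plate 2. Genes varying with time ran from 7619 to 8812 in the control and from 8103 to 9142 in the chimera.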

Other observations

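At 4 h further members of the fixed lists were called singly while their lists were not, or, for the discoidin gene dscE, while its list was too small to test. As 13.59% of all genes tested were called at 4 h, single calls in a list say little about the list. The histidine kinase gene dhkC (0.89 ± 0.16, log2 and SE), tagA (0.47 ± 0.12), the group size gene smlA (1.01 ± 0.23), the adenylyl cyclase regulator gene dagA (0.84 ± 0.24), alyL (0.61 ± 0.13), dscE (0.97 ± 0.21), fadA (0.49 ± 0.13), mybE (0.65 ± 0.15) and cbpB (0.59 ± 0.14) were higher in the chimera. Lower were dmtA, a methyltransferase gene of DIF synthesis (-0.995 ± 0.23), stkA (-1.01 ± 0.28), psiB (-1.06 ± 0.29), pspC (-0.36 ± 0.10), alrA (-0.998 ± 0.20), expl8 (-0.92 ± 0.20), ctsD (-0.61 ± 0.17) and hspA (-0.46 ± 0.12).

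The genes called at 4 h had little common shift in their 4 h direction later on. Of the 1419 genes called at 4 h, 65.6% had the same direction at 8 h, 52.5% at 12 h, 70.7% at 16 h and 41.6% at 20 h. The median absolute difference of these genes was 0.61 (log2) at 4 h. The median signed difference, turned to the direction of 4 h, was 0.05, 0.01, 0.09 and -0.03 at these later times. These signed medians are not sizes, since opposite directions cancel in them. The genes were also chosen for their difference at 4 h, so part of the drop is built in. At 16 h the difference between chimera and control had a correlation of 0.714 across genes outside the ribosomal list with the control's own change from 12 to 20 h (slope 0.262), against 0.296 at 12 h and 0.107 at 8 h for the corresponding changes. Genes are not independent replicates, and 2 plates per group were set against each other here. A stage difference between chimera and control plates at 16 h stays open beside an effect of the partner.

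The number of genes called for the mean over times was set against other splits of the plates within times, with the real split and 99 others drawn from 3888. Of the 100 splits 7 called at least the 345 genes of the real split, which is one of them. By the bound set beforehand, this many splits meant that chance could give the count. The highest other called 1504 and the median of the others was 0. All 7 parted the plates of 4 h as in the real split and so carry the real difference at 4 h. These splits therefore cannot tell chance from that difference, and chance stays open for this count. The 64 splits that part the plates of 4 h otherwise called at most 6 genes. Splits with several times the real count point to a structure of the samples, and the highest parted 3 times as in the real split and 2 by replicate number.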
